A study of Mus musculus with 9 samples.

How the data were processed

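Dorsal skin from 9 mice was profiled by RNA sequencing, with 3 libraries in each of 3 groups. Groups and replicate numbers were taken from the sample titles. The labels call the replicates biological and name mice as the treated units. Separate animals are implied by this and not stated sample by sample. The p-values of the tests of single genes measure the spread between these samples. All 9 carry 1 batch label, and no split by batch was available. Untreated mice were not stated to be depilated or not. The donor cells were HFSCs grown with 200 ng/mL Wnt3a, per the labels' protocols, and skin was taken at day 14.

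Libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, FastQC 0.11.9 and RSEM 1.3.3, and the builds GRCm38 and mm10, with no order or settings; the aligner and the annotation release were not given in the sources used here. The deposited values are expected counts per gene from RSEM, per the file headers and the submitters' processing notes, not normalized, for 78317 Ensembl genes in 9 libraries. The table also held 3 group mean columns, which equalled the means of their libraries within 0.0001 and were not used. Between 23.0% and 25.6% of detected genes had a value that was not exactly whole, with no tolerance. Reads shared between near-identical genes are divided by RSEM's estimate, so single keratin-associated proteins, stefins and major urinary proteins carry more uncertainty than their families. Values were rounded to whole numbers for testing. Symbols, KEGG pathways and gene ontology terms came from annotation columns of the same table; 21909 genes had no symbol and 627 rows shared one. Of the IDs, 51487 were in GENCODE M21 and 26830 were not, so that release is not the one used for the table. The table holds no coordinates, and none are printed.

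Library totals ran from 17356298 to 21336815 counts. Genes were kept by edgeR's filterByExpr with the groups as argument, which left 17728. TMM factors ranged from 0.943 to 1.08. A quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust estimation was fitted to all 9 libraries, which share 1 estimate of the spread because groups hold 3 libraries each; the common dispersion was 0.0289. The 3 contrasts were blank patch minus untreated, patch with cells minus blank patch, and patch with cells minus untreated. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes, with no fold threshold. CPM values use TMM-scaled library sizes, errors are SD over 3 libraries or SE of the fitted log2 fold change as marked, and principal components used log2 CPM with a prior count of 2. Where a group had 0 counts in all 3 libraries, the fold was computed against a floor of 3 counts per library and is a lower bound; with 1 to 3 counts in a group, the ratio is given with an exact 95% interval. Floors and intervals cover counting error only.

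Gene lists were fixed before the data were examined: 39 lists of follicle parts, signalling pathways, cell types of skin and technical groups. Each was tested with camera at a preset correlation between genes of 0.01 and, as an alternative, with a correlation estimated per list and with fry, adjusted over the lists of a comparison. Members were counted as higher or lower after adjustment over all tested genes and, separately, adjusted over the list alone. Terms of 10 to 500 tested genes were tested by a one-sided Fisher exact test of called higher and called lower genes against the tested genes annotated in the same family. This test takes genes as independent units, so its p-values do not measure the spread between samples. Named genes followed a rule fixed at the same time: the 6 called genes with the highest and the 6 with the lowest fold change with a mean of at least 5 CPM in the higher group, no overlap of libraries and a symbol that is not a predicted gene; up to 3 called members with the smallest p from each list; and Lef1, Shh, Wnt10b, Axin2, Mki67, Lgr5, Cd34, Krt15, Sox9, Fgf7, Vegfa, Bmp4, Fgf18 and Tyrp1 whether called or not.

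The scripts were tested on simulated counts drawn from the libraries' means, sizes and dispersions with 200 genes changed. For the patch with cells against the blank patch, with 17363 genes tested, 17.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold were called in the right direction, and 9 unchanged genes were called. For blank patch against untreated, with 17352 genes tested, these shares were 34.3%, 67.2% and 93.9%, with 5 unchanged genes called; for patch with cells against untreated, with 17355 genes tested, they were 38.8%, 80.6% and 90.9%, with 1. A list moved in each simulation was called and no other list was. Genes were drawn independently of each other, so this does not show how often camera calls lists of correlated genes. Far fewer genes were changed than were called in the data, so the shares above are not the sensitivity in the data.

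Alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, RLE and upper-quartile factors, TMM without the hair genes, no count filter, a filter of 1 CPM in 3 libraries, a fit on the 6 libraries of a comparison, the replicate number as a block, a test against a 1.5-fold change, and leaving out each library. Replicates were compared before use: no pair of libraries held identical values, and their counts differed beyond sampling noise, with chi-square values per gene between 6.23 and 46.8. The estimated correlation, fry and DESeq2 (no adjusted p for 18 genes in each comparison, left as missing) completed the set. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.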

Results

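Gene expression was measured by RNA sequencing of stranded mRNA libraries from whole dorsal skin of C57 mice that were 7 weeks old when treated. Skin was taken 14 days after treatment. The 9 libraries fell into 3 groups of 3. Untreated mice formed the blank control. A second group was depilated and given a cryoMN patch without cells, called the blank patch below, which the labels name the positive control. The remaining group was depilated and given the same kind of patch loaded with hair follicle stem cells (HFSCs) that had been cultured with 200 ng/mL Wnt3a, a Wnt ligand. It is called the patch with cells below. Library totals ranged from 17356298 to 21336815 expected counts, and 17728 genes were tested. The first principal component of the log2 CPM values held 75.9% of the variance. It placed the untreated libraries between -118 and -111, the blank patch libraries between 2.24 and 34.8, and the libraries from the patch with cells between 86.2 and 97.8.

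The hair shaft keratins, keratin-associated proteins and inner root sheath genes of the fixed lists, which build the hair fibre and the sheath that moulds it, together held 0.0487% ± 0.0066 of all counts in untreated skin, 2.36% ± 0.746 under the blank patch and 6.60% ± 1.12 under the patch with cells (SD, n = 3 in each group). The share of counts from the mitochondrial genome moved the other way, from 3.71% ± 0.499 to 2.80% ± 0.229 and 2.12% ± 0.175 (SD, n = 3 in each group).

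**Figure D1:**
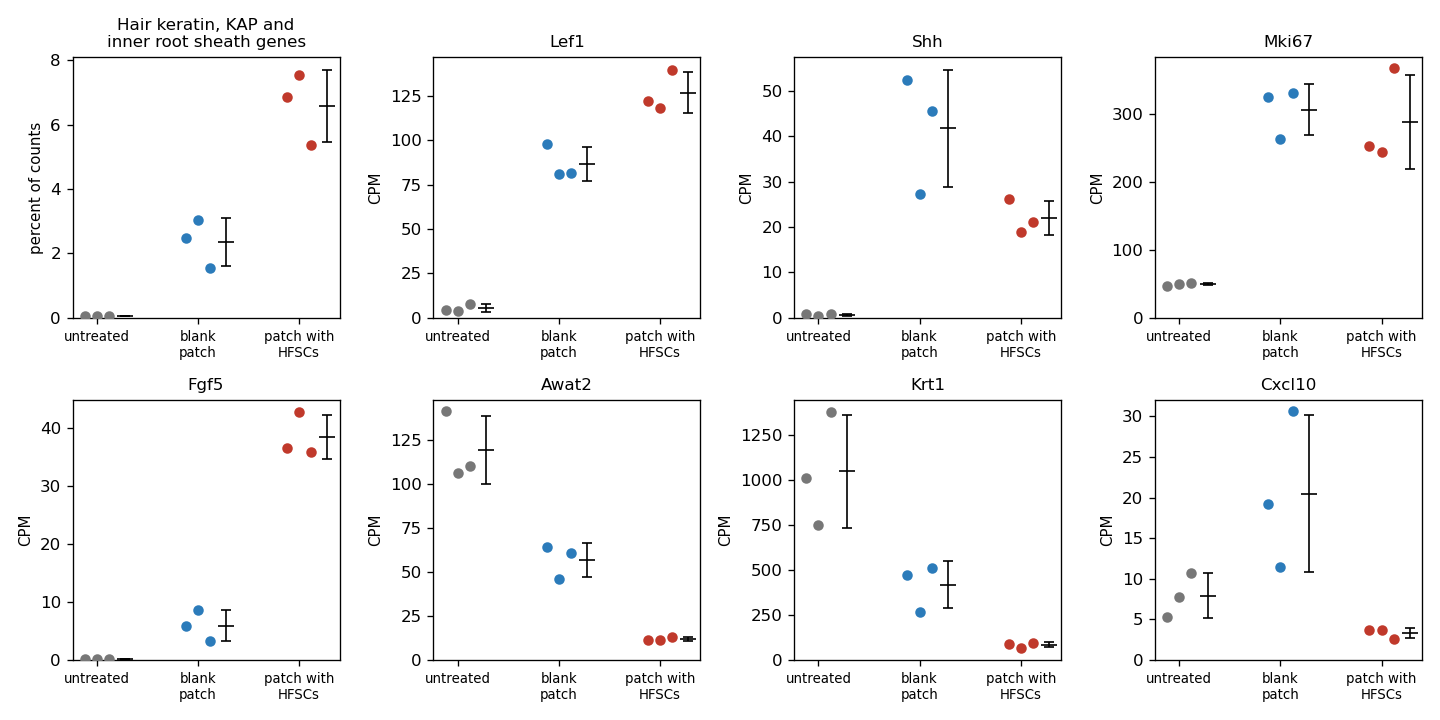
Share of counts in hair keratin, keratin-associated protein (KAP) and inner root sheath genes (percent of counts), and expression of 7 named genes (CPM), in each library of the 3 groups; coloured points are libraries, and the black bar beside them is the group mean with its SD (n = 3). The hair gene share was 2.36% under the blank patch and 6.60% under the patch with cells, Mki67 was at 306 and 288 CPM, and Krt1 was at 418 and 84.8 CPM.

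The first comparison, blank patch against untreated skin, asks what depilation and a cell-free patch changed by day 14. Genes of the growing hair follicle rose. Krt73 and Krt85, keratins of the inner root sheath and of the hair shaft, were at 0 counts in all 3 untreated libraries and reached 789 ± 122 and 442 ± 108 CPM under the blank patch (SD, n = 3), at least 5320-fold and at least 2980-fold higher against a floor of 3 counts per library. Shh, the hedgehog ligand of the hair matrix (ENSMUSG00000002633), rose from 0.692 ± 0.212 to 41.7 ± 12.9 CPM, and Lef1, a transcription factor of the Wnt pathway in matrix and dermal papilla (ENSMUSG00000027985), from 5.53 ± 2.19 to 86.8 ± 9.52 CPM (SD, n = 3). The proliferation marker Mki67 (ENSMUSG00000031004) rose from 49.8 ± 2.05 to 306 ± 37.5 CPM (SD, n = 3). Many markers of immune cells, fat, sebaceous gland and skeletal muscle fell, though the neutrophil and acute inflammation list was not called. The list calls depended on the correlation assumed between genes, as given below.

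In the edgeR quasi-likelihood test 9518 of 17728 genes passed, 4903 higher and 4615 lower under the blank patch. The larger direction turned under upper-quartile scaling, with 4299 higher and 5334 lower, and under the filter of 1 CPM in 3 libraries, with 4644 and 4659. Of the tested hair shaft keratins 15 of 16 rose, or 16 when adjusted over the list alone, with a median log2 fold change of 10.42, or 8.55 with the members at 0 counts set at their bound. The keratin-associated proteins, the matrix proteins that crosslink hair keratins, rose in 25 of 39 members, or 29 adjusted over the list alone. At 0 counts in all untreated libraries were 37 of them, and with these at their bound the list's median was 6.83. Of the inner root sheath genes 16 of 17 rose on either adjustment. Krt25 had 3 counts in the untreated group and 209418 under the blank patch, a ratio of 67920 with a 95% counting interval of 23240 to 329400. The camera calls of these 3 lists were lost, at adjusted p = 0.177, 0.413 and 0.0686 with an estimated correlation.

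All 21 hair matrix and differentiation regulators rose, on either adjustment, with a median log2 fold change of 3.28 (adjusted p = 0.0686 with an estimated correlation). Among them Msx2 rose by a log2 fold change of 5.81 ± 0.188, Dlx3 by 5.62 ± 0.193 and Hoxc13, a regulator of hair keratin genes, by 5.00 ± 0.185 (SE; edgeR adjusted p = 2.81e-08, 3.83e-08 and 4.96e-08). All 36 cell cycle genes rose, on either adjustment, with a median of 2.29 (adjusted p = 0.177 with an estimated correlation), among them Top2a from 45.2 to 266 CPM. The melanocyte and pigment list rose in 15 of 18 members, on either adjustment, with Tyr, the rate-limiting enzyme of melanin synthesis, from 1.63 ± 0.339 to 50.5 ± 11.8 CPM (SD, n = 3; list adjusted p = 0.177 with an estimated correlation). In the outer root sheath list 8 of 12 members rose and 1 fell, on either adjustment (adjusted p = 0.233 with an estimated correlation). Its companion layer keratin Krt75 rose by a log2 fold change of 3.95 ± 0.212 (SE).

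The Wnt list had 21 of 33 members higher and 4 lower, or 22 and 4 adjusted over the list alone (adjusted p = 0.233 with an estimated correlation). Nkd2, a feedback inhibitor of Wnt signalling, rose from 24.3 to 109 CPM, and Wnt10b from 4.88 ± 0.142 to 25.9 ± 7.91 CPM (SD, n = 3). Axin2, a direct Wnt target, rose by only 0.48 ± 0.103 (log2, SE; edgeR adjusted p = 0.00256). Hedgehog genes had 10 of 13 members higher and 3 lower, Notch genes 9 of 15 higher and 4 lower, and BMP and TGF-beta genes 12 of 27 higher and 4 lower, all on either adjustment (adjusted p = 0.177, 0.233 and 0.323 with an estimated correlation). The BMP and TGF-beta list also missed camera's threshold without untreated replicate 1 and without blank patch replicate 2, at adjusted p = 0.0679 and 0.0964. Its alternatives ranged from 0.000918 to 0.323. The list of FGF, EGF and IGF growth factors was not called (camera adjusted p = 0.407), with 11 of 25 members higher and 8 lower, or 11 and 9 adjusted over the list alone. Its median was below 0 at -0.26 while its mean was above it at 0.49.

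In the bulge and hair germ list 13 of 24 members rose and 6 fell, on either adjustment (adjusted p = 0.323 with an estimated correlation). Lgr5, which marks cycling follicle stem cells and the lower outer root sheath, rose from 13.3 ± 0.970 to 56.2 ± 1.92 CPM, whereas Cd34 fell from 498 ± 68.6 to 230 ± 37.9 CPM and Krt15 from 1055 ± 86.5 to 557 ± 92.9 CPM (SD, n = 3). Both are used as markers of bulge cells, but values from whole skin do not show which cells changed. The dermal papilla list had 14 of 29 members higher and 1 lower, or 15 and 2 adjusted over the list alone (adjusted p = 0.233 with an estimated correlation), with Corin up by 3.87 ± 0.247 (log2, SE). Fgf7 was at 20.3 ± 2.04 CPM against 24.99 ± 4.52 in untreated skin and did not pass (SD, n = 3; edgeR adjusted p = 0.139).

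Immune lists fell. Macrophage and monocyte genes were lower in 21 of 24 members and higher in 2, on either adjustment, with Ccr2, a monocyte chemokine receptor, at 26.4 ± 5.56 against 115 ± 19.1 CPM (SD, n = 3). Langerhans and dendritic cell genes were lower in 14 of 16 with 1 higher, the interferon response in 27 of 29 with 1 higher, complement and MHC class I genes in all 21, and T, NK and B cell genes in 15 of 26 with none higher, again on either adjustment. These 5 lists had adjusted p = 0.233, 0.233, 0.233, 0.233 and 0.323 with an estimated correlation, in the order given. Mast cell genes fell in 8 of 12 members with 1 higher, or 9 and 1 adjusted over the list alone (adjusted p = 0.413 with an estimated correlation). The neutrophil and acute inflammation list was not called (camera adjusted p = 0.459), with 7 of 17 members higher and 3 lower on either adjustment. Its median was -0.02 and its mean 0.42. Its higher members included the chemokines Ccl2, at 22.4 ± 6.26 against 6.46 ± 0.534 CPM, and Cxcl1, at 4.11 ± 1.43 against 0.346 ± 0.215 CPM (SD, n = 3).

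Marker genes of tissue outside the follicle were lower as well. These values are relative to all counts, in which follicle genes rose, and dilution was not tested in this comparison. Sebaceous gland genes fell in 18 of 23 members and rose in 2, on either adjustment, and adipocyte genes fell in 18 of 20, or 19 adjusted over the list alone (adjusted p = 0.233 and 0.323 with an estimated correlation). Plin1, which coats fat droplets, went from 267 ± 66.4 to 90.5 ± 15.7 CPM (SD, n = 3). Skeletal muscle genes fell in 23 of 30 members, or 24 adjusted over the list alone, and blood vessel genes in 16 of 25, or 17 adjusted over the list alone (adjusted p = 0.413 and 0.233 with an estimated correlation). Schwann cell and nerve genes fell in 10 of 18 members and rose in 5, on either adjustment (adjusted p = 0.233 with an estimated correlation). Fibroblast and matrix genes (12 of 30 lower, 3 higher), smooth muscle and pericytes (9 of 15 lower, 3 higher) and brown and beige adipocytes (5 of 9 lower, 1 higher) were not called by camera, at adjusted p = 0.0613, 0.104 and 0.089, with the same counts adjusted over the list alone. Camera called the matrix list, lower, without untreated replicate 1 (adjusted p = 0.00803), without blank patch replicate 3 (0.0474), with the replicate number as a block (0.0325) and with no count filter (0.0281). It called the brown adipocyte list, lower, without untreated replicates 2 or 3 (adjusted p = 0.0379 and 0.0186) and with no count filter (0.0187). Fry called the brown adipocyte and smooth muscle lists, lower, at adjusted p = 0.00062 and 0.0166. Tnc, a matrix protein, was among the 3 higher matrix genes, from 14.2 ± 2.42 to 139 ± 54.3 CPM (SD, n = 3).

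Differentiated interfollicular epidermis was not called (15 of 29 lower and 6 higher, or 16 and 6 adjusted over the list alone; camera adjusted p = 0.138), nor were wound keratinocyte genes (5 of 20 higher and 4 lower on either adjustment; camera adjusted p = 0.485). Basal keratinocyte genes rose in 6 of 15 members and fell in 1, on either adjustment. The camera call was lost without untreated replicate 2, at adjusted p = 0.0532, and at adjusted p = 0.233 with an estimated correlation. Of the technical lists, heat shock and immediate early genes rose in 13 of 23 members with 1 lower on either adjustment, mitochondrial genome transcripts fell in 10 of 13, or 11 adjusted over the list alone, and nuclear oxidative phosphorylation genes fell in 22 of 35, or 24 adjusted over the list alone (adjusted p = 0.372, 0.323 and 0.534 with an estimated correlation). Ribosomal protein genes were not called (camera adjusted p = 0.645; 5 of 60 higher, 1 adjusted over the list alone), nor were catagen and apoptosis genes (camera adjusted p = 0.368), of which 9 of 23 were higher and 5 lower, or 9 and 6 adjusted over the list alone. The catagen list had a median of -0.18 and a mean of 0.34, and fry called it higher (adjusted p = 0.00482). Over gene ontology terms, called higher genes were enriched in cell division (182 of 300 members, 2.05 times the expected number, Fisher adjusted p = 5.78e-26) and mRNA splicing (86 of 121, adjusted p = 6.98e-18). Called lower genes were enriched in oxidation-reduction (69 of 110, adjusted p = 6.93e-13) and innate immune response (123 of 270, adjusted p = 2.63e-09). The Fisher tests of terms take genes as independent and do not measure the spread between mice. None of the 29 lists called by camera in this comparison kept its call with an estimated correlation. The labels do not say whether untreated mice were depilated, so this comparison does not separate hair removal from the patch.

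The comparison of the patch with cells against the blank patch asks what the loaded cells, cultured with Wnt3a, added. No group was given cells cultured without Wnt3a, or Wnt3a without cells, so their parts cannot be told apart. Hair shaft and inner root sheath genes were higher still with cells, while the cell cycle list was not called. Mki67 was at 288 ± 69.0 CPM with cells and 306 ± 37.5 without (SD, n = 3; edgeR adjusted p = 0.703). Fgf5, the growth factor that ends the growth phase of the hair cycle (ENSMUSG00000029337), rose from 5.92 ± 2.67 to 38.4 ± 3.79 CPM, and Krt85 (ENSMUSG00000116336) from 442 ± 108 to 1023 ± 53.4 CPM (SD, n = 3). Awat2, a wax synthase of the sebaceous gland (ENSMUSG00000031220), fell from 57.0 ± 9.64 to 12.2 ± 1.06 CPM, and Krt1, the keratin of differentiating epidermis (ENSMUSG00000046834), from 418 ± 130 to 84.8 ± 13.5 CPM (SD, n = 3). Dermal papilla, extracellular matrix, muscle and immune genes fell in part.

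The edgeR quasi-likelihood test called 4650 genes, 2166 higher and 2484 lower with cells, of which 493 and 989 differed by more than 2-fold. Counts fell to 2438 without blank patch replicate 3, 2739 without replicate 1 of the patch with cells and 2433 without its replicate 2. Upper-quartile scaling called 4679 genes, 33.4% of them higher in place of 46.6%.

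Of 16 hair shaft keratins 12 rose, or 15 adjusted over the list alone, with a median log2 fold change of 2.33, and 14 of 17 inner root sheath genes rose on either adjustment, with a median of 1.46 (adjusted p = 0.347 for both with an estimated correlation). Krt28 went from 508 ± 89.8 to 1525 ± 371 CPM and Padi3, which citrullinates sheath and hair proteins, from 265 ± 84.9 to 810 ± 120 CPM (SD, n = 3). Keratin-associated proteins rose in 7 of 39 members, or 6 adjusted over the list alone, around a median of 2.96 (adjusted p = 0.480 with an estimated correlation). Krtap17-1 went from 10.7 ± 4.20 to 70.1 ± 31.7 CPM (SD, n = 3). Matrix regulators rose in 12 of 21 members and fell in 1, or 17 and 3 adjusted over the list alone (adjusted p = 0.415 with an estimated correlation). Foxn1 and Foxq1, transcription factors needed for a normal hair shaft, rose from 34.2 ± 5.97 to 78.2 ± 8.51 CPM and from 34.8 ± 7.31 to 104.5 ± 24.4 CPM (SD, n = 3; edgeR adjusted p = 0.00169 and 0.00172). The member that fell was Shh, at 22.0 ± 3.68 against 41.7 ± 12.9 CPM (SD, n = 3; edgeR adjusted p = 0.017). This call ended without blank patch replicate 3 and without replicates 2 and 3 of the patch with cells (edgeR adjusted p = 0.064, 0.0726 and 0.0509), with alternatives from 7.21e-10 to 0.266, the latter against a 1.5-fold change. Lef1 was at 127 ± 11.5 against 86.8 ± 9.52 CPM (SD, n = 3) and did not pass (edgeR adjusted p = 0.0687). DESeq2 called it higher, at adjusted p = 0.0245, as did the edgeR fits on the 6 libraries alone, at 0.00907, and with no count filter, at 5.36e-05, and its highest p, against a 1.5-fold change, was 1. The outer root sheath list was not called (camera adjusted p = 0.0953; 3 of 12 higher, and 1 lower when adjusted over the list alone) but passed as higher without blank patch replicate 2, at 0.0145, and with no count filter, at 0.0217. Within it Krt75 rose from 472 ± 98.7 to 1114 ± 50.1 CPM (SD, n = 3). Pigment genes rose in 4 of 18 members on either adjustment. Their camera call was lost without blank patch replicate 2, at adjusted p = 0.0744, fry did not call them (0.114), and the call was lost at adjusted p = 0.560 with an estimated correlation.

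None of the 36 cell cycle genes passed in edgeR, on either adjustment, and 0 had an unadjusted p under 0.05, in edgeR and in DESeq2 alike. The list was not called (camera adjusted p = 0.681) with all libraries, but was called lower without blank patch replicate 2, at 0.0344, and its sign was not stable when other libraries were left out. Over all 17728 genes 7030 had an unadjusted p under 0.05. The Wnt list had 5 of 33 members higher and 5 lower on either adjustment and was not called (camera adjusted p = 0.539). Rspo4, a secreted amplifier of Wnt signals that stands in the dermal papilla list, rose from 4.71 ± 1.73 to 20.2 ± 1.94 CPM (SD, n = 3). Axin2 was at 66.2 ± 3.88 against 49.4 ± 5.22 CPM (SD, n = 3), called with all libraries (edgeR adjusted p = 0.0134, alternatives from 0.00228 to 1) but not without blank patch replicate 3 or replicate 1 of the patch with cells (edgeR adjusted p = 0.0541 and 0.0561). Hedgehog genes fell in 4 of 13 members on either adjustment, among them Hhip, a hedgehog target and inhibitor, from 33.1 ± 8.26 to 12.5 ± 1.36 CPM (SD, n = 3; list adjusted p = 0.492 with an estimated correlation). The Hedgehog call was also lost without blank patch replicates 1 or 3, at adjusted p = 0.11 and 0.0717, and without replicate 1 of the patch with cells, at 0.0711, with alternatives from 0.00248 to 0.492. BMP and TGF-beta genes (7 of 27 higher and 4 lower, or 9 and 5 adjusted over the list alone), growth factors (4 of 25 higher and 7 lower, or 4 and 8), Notch genes (3 of 15 higher and 2 lower on either adjustment) and catagen genes (3 of 23 higher and 6 lower, or 4 and 8) were not called by camera, at adjusted p = 0.539, 0.576, 0.592 and 0.576. The Wnt, BMP and Notch lists had medians of 0.10, 0.11 and 0.15 and means of -0.07, -0.04 and -0.06.

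Dermal papilla genes fell in 15 of 29 members and rose in 3, or 16 and 4 adjusted over the list alone (adjusted p = 0.347 with an estimated correlation). Fgf7 fell from 20.3 ± 2.04 to 7.71 ± 1.22 CPM and Alpl, the alkaline phosphatase used as a papilla marker, from 20.7 ± 3.97 to 9.19 ± 0.689 CPM (SD, n = 3). Bulge and hair germ genes fell in 9 of 24 members, or 10 adjusted over the list alone, with Lgr5 at 40.1 ± 3.62 against 56.2 ± 1.92 CPM (SD, n = 3; list adjusted p = 0.495 with an estimated correlation). Cd34 was called lower with all libraries, at 145.5 to 173.8 CPM per library with cells against 187.7 to 261.2. This call ended without blank patch replicates 2 or 3 (edgeR adjusted p = 0.0518 and 0.0999). It also ended without replicates 2 or 3 of the patch with cells (0.0914 and 0.0565). Krt15 and Sox9 did not pass (edgeR adjusted p = 0.223 and 0.0949), with 462 ± 79.9 against 557 ± 92.9 CPM and 159 ± 17.42 against 125 ± 3.81 CPM (SD, n = 3). Sox9 was called higher by edgeR with no count filter (adjusted p = 0.0235) and on the 6 libraries alone (0.0308), with 1 as its highest p, against a 1.5-fold change. Vegfa, Bmp4, Fgf18, Tyrp1 and Wnt10b did not pass either (edgeR adjusted p = 0.524, 0.775, 0.365, 0.188 and 0.0978), though Wnt10b passed, lower, without blank patch replicate 2 (0.0119) and with no count filter (0.0191). Tyrp1 was called higher by edgeR with the replicate number as a block (adjusted p = 0.0307) and with no count filter (0.0253).

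Sebaceous gland genes fell in 17 of 23 members and rose in 1, or 18 and 1 adjusted over the list alone, with a median log2 fold change of -1.14 (adjusted p = 0.333 with an estimated correlation). Elovl4, which extends fatty acids, and Far2, which makes fatty alcohols, fell by 1.77 ± 0.174 and 1.84 ± 0.164 on the log2 scale (SE; edgeR adjusted p = 0.000356 and 0.000314). Fibroblast and matrix genes fell in 19 of 30 members and rose in 1, or 24 and 1 adjusted over the list alone (adjusted p = 0.347 with an estimated correlation), among them Col5a1 from 311 ± 54.4 to 142 ± 3.48 CPM and Postn from 892 ± 170 to 390 ± 35.3 CPM (SD, n = 3). Skeletal muscle genes fell in 14 of 30 members, or 22 adjusted over the list alone, smooth muscle and pericyte genes in 8 of 15, or 12, and blood vessel genes in 7 of 25, or 8, with none higher in any of these (adjusted p = 0.480, 0.347 and 0.455 with an estimated correlation). Brown and beige adipocyte genes fell in 4 of 9 members and rose in 1, or 5 and 1 adjusted over the list alone (adjusted p = 0.347 with an estimated correlation). Of the genes that fell, 2, Cidea and Elovl3, also stand in the sebaceous list. The adipocyte call, with 6 of 20 members lower or 8 adjusted over the list alone, was lost without blank patch replicate 2, at camera adjusted p = 0.159, in fry, at 0.173, and at adjusted p = 0.697 with an estimated correlation. Schwann cell (4 of 18 lower and 1 higher, or 5 and 1 adjusted over the list alone) and mast cell genes (1 of 12 lower and 1 higher on either adjustment) were not called by camera, at adjusted p = 0.149 and 0.280. The Schwann cell list was called lower with no count filter (camera adjusted p = 0.048) and by fry (0.0181).

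Differentiated epidermis moved both ways, with 18 of 29 members lower and 8 higher on either adjustment (adjusted p = 0.560 with an estimated correlation). Involucrin, Ivl, a precursor of the cornified envelope, rose from 91.8 ± 9.34 to 202 ± 30.3 CPM against the fall of Krt1 (SD, n = 3). The list's camera call was lost without replicate 3 of the patch with cells, at adjusted p = 0.0906, and fry did not call it (0.0797), with alternatives from 4.36e-07 to 0.56. Basal keratinocyte (3 of 15 higher and 3 lower) and wound keratinocyte genes (5 of 20 higher and 5 lower), both counted alike on either adjustment, were not called by camera, at adjusted p = 0.869 and 0.539. The wound list was called higher without blank patch replicate 2, at camera adjusted p = 0.0145.

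The interferon response fell in 12 of 29 members, or 13 adjusted over the list alone, complement and MHC class I genes in 13 of 21, or 15, and T, NK and B cell genes in 13 of 26, or 17, with none higher (adjusted p = 0.455, 0.455 and 0.368 with an estimated correlation). Cxcl9 and Cxcl10, chemokines that draw T cells, went from 11.5 ± 4.45 to 1.59 ± 0.303 CPM and from 20.4 ± 9.65 to 3.36 ± 0.619 CPM (SD, n = 3). Langerhans and dendritic cell genes fell in 11 of 16 members with none higher, or 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.415 with an estimated correlation). Macrophage genes fell in 7 of 24 members and rose in 2 on either adjustment. The camera call was lost without blank patch replicate 2, at adjusted p = 0.0744, in fry, at 0.124, and at adjusted p = 0.628 with an estimated correlation. Its higher members were Gpnmb, from 167 ± 35.8 to 519 ± 41.8 CPM, and Arg1, from 19.6 ± 4.33 to 44.6 ± 8.78 CPM (SD, n = 3). Gpnmb is also made by pigment cells. The neutrophil and inflammation list fell in 7 of 17 members on either adjustment, with Ccl2 at 5.25 ± 1.29 against 22.4 ± 6.26 CPM (SD, n = 3). Its camera call was lost under upper-quartile scaling (adjusted p = 0.0627), under the stricter count filter (0.0652) and without blank patch replicate 2 (0.103), and at adjusted p = 0.492 with an estimated correlation.

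Ribosomal protein genes rose in 19 of 60 members, or 45 adjusted over the list alone, around a median log2 fold change of 0.41 (adjusted p = 0.531 with an estimated correlation). Fry did not call the list (adjusted p = 0.0505). Rpl12 was at 44.0 ± 5.04 against 29.9 ± 5.41 CPM (SD, n = 3; edgeR adjusted p = 0.0165), a call that ended without blank patch replicate 3 (0.0604) and without replicates 1 or 2 of the patch with cells (0.0704 and 0.0564). Called higher genes were enriched in rRNA processing (44 of 98 members, 3.49 times the expected number, Fisher adjusted p = 1.08e-11) and in translational initiation (16 of 24, adjusted p = 1.13e-06). Called lower genes were enriched in immune response (65 of 151, adjusted p = 1.16e-13) and extracellular matrix organization (47 of 108, adjusted p = 5.91e-10). As above, the Fisher p-values take genes as independent and do not measure the spread between mice. Heat shock and immediate early genes (6 of 23 higher and 2 lower on either adjustment), nuclear oxidative phosphorylation (2 of 35 higher, none adjusted over the list alone) and mitochondrial genome transcripts (0 of 13 on either adjustment) were not called by camera, at adjusted p = 0.141, 0.0661 and 0.339. Of the mitochondrial transcripts 3 had an unadjusted p under 0.05 in edgeR, and DESeq2 called 3. Camera called the heat shock list higher without blank patch replicate 1 (adjusted p = 0.0364), and the oxidative phosphorylation list higher without that library (0.00888), without replicate 3 of the patch with cells (0.0166), with the replicate number as a block (0.0354) and with no count filter (0.013). All 24 lists called by camera here lost the call with an estimated correlation.

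**Figure D2:**
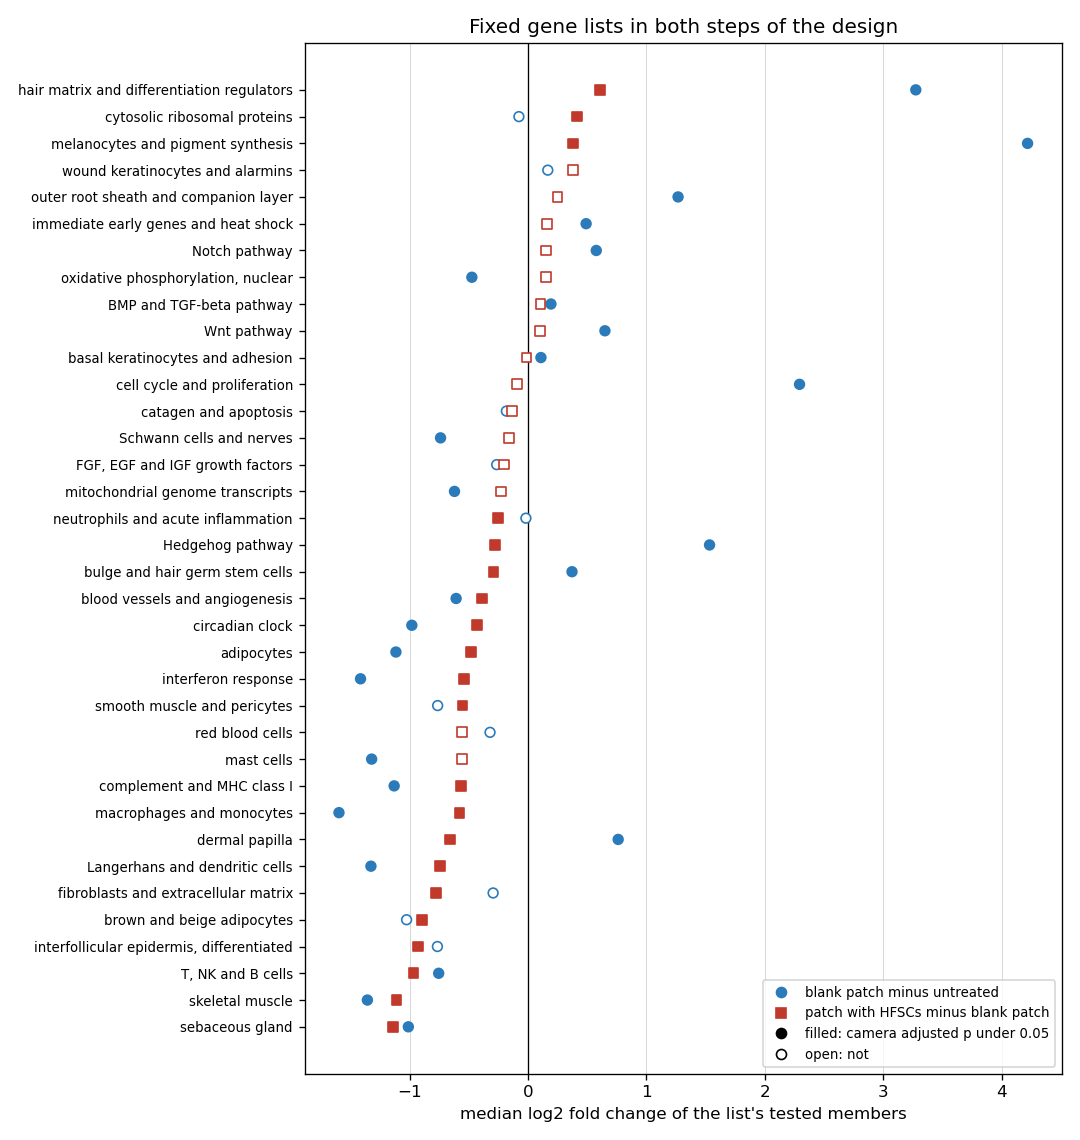
Median log2 fold change of the tested members of 36 fixed gene lists, blank patch minus untreated (circles) and patch with cells minus blank patch (squares), with members at 0 counts in a group set at their bound; filled points passed camera at an adjusted p under 0.05 with the preset correlation. The 3 lists of hair fibre and inner root sheath genes are left out for scale. The sebaceous gland list had a median of -1.14 and the matrix regulators one of 0.61 in the second step, and the cell cycle list moved from 2.29 to -0.09.

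The whole treatment, patch with cells against untreated skin, gave the widest differences. All 16 hair shaft keratins, all 39 keratin-associated proteins and all 17 inner root sheath genes rose, on either adjustment. Krt72 and Krtap7-1, at 0 counts in all untreated libraries, were at least 10300-fold and at least 6720-fold higher, at 1529 ± 542 and 997 ± 205 CPM (SD, n = 3). Fgf5 went from 0.231 ± 0.0288 to 38.4 ± 3.79 CPM and Tyr from 1.63 ± 0.339 to 68.1 ± 11.1 CPM (SD, n = 3). All 29 interferon response genes and all 21 complement and MHC class I genes fell on either adjustment, as did 29 of 30 skeletal muscle genes and 27 of 30 matrix genes, with 2 matrix genes higher.

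The edgeR quasi-likelihood test called 12195 genes, 6114 higher and 6081 lower. The larger direction turned under the filter of 1 CPM in 3 libraries (5675 higher and 5776 lower), against a 1.5-fold change (3281 and 4089), and without untreated replicate 1 (5637 and 5824), 2 (5550 and 5770) or 3 (6033 and 6083) or replicate 2 of the patch with cells (5590 and 5691). It also turned under upper-quartile scaling, which called 5006 higher and 7082 lower and shifted the median log2 fold change of all genes by -0.17 against TMM. The hair fibre, keratin-associated protein and inner root sheath lists had adjusted p = 0.226, 0.378 and 0.167 with an estimated correlation, and the interferon, complement, muscle and matrix lists 0.248, 0.248, 0.360 and 0.298. The 21 matrix regulators and 36 cell cycle genes all rose, on either adjustment, as did 17 of 18 pigment genes (adjusted p = 0.167, 0.248 and 0.226 with an estimated correlation). Sebaceous gland genes fell in 20 of 23 members with 2 higher, adipocyte genes in 18 of 20, macrophage genes in 22 of 24 with 2 higher, and T, NK and B cell genes in 24 of 26, on either adjustment (adjusted p = 0.226, 0.372, 0.298 and 0.248 with an estimated correlation). Dcn, a small matrix proteoglycan, fell from 2872 ± 65.3 to 896 ± 59.0 CPM, and Awat2 from 119 ± 19.2 to 12.2 ± 1.06 CPM (SD, n = 3). The dermal papilla and bulge lists, with 12 of 29 higher and 10 lower and with 11 of 24 higher and 9 lower on either adjustment, were not called (camera adjusted p = 0.316 and 0.337), but fry called both higher (adjusted p = 0.00841 and 0.0187). Within them Lgr5 rose by 1.59 ± 0.1 and Fgf7 fell by 1.70 ± 0.167 (log2, SE; edgeR adjusted p = 5.17e-07 and 7.46e-06). The other lists called higher, among them the Wnt list with 22 of 33 members higher and 6 lower and the Hedgehog list with 9 of 13 higher and 3 lower on either adjustment, and the other lists called lower, among them blood vessels with 21 of 25 lower and Langerhans and dendritic cells with 15 of 16 lower and 1 higher on either adjustment, also lost their camera calls, at adjusted p = 0.226 to 0.788 with an estimated correlation. Differentiated epidermis, with 18 of 29 members lower and 9 higher on either adjustment, lost its camera call under upper-quartile scaling (adjusted p = 0.053) and without replicate 3 of the patch with cells (0.0809). Ribosomal protein genes, with 25 of 60 higher or 24 adjusted over the list alone, lost it without untreated replicate 3 (0.0541) and without replicate 1 of the patch with cells (0.0604).

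Both treatments moved largely overlapping sets of genes against untreated skin. Of the genes called in both comparisons, 4514 were higher in both, 4215 lower in both and 41 moved in opposite directions. Independent lists of the same sizes would share 1691, 1583 and 3273. The fold changes correlated across genes at 0.932, against a mean of 0.500 over 20 simulated draws of unchanged groups set against the same untreated libraries, and their covariance was 2.45 against 0.0503. Genes are not independent replicates. Both comparisons use the same 3 untreated libraries, which cannot be halved with 2 libraries on each side, so the share of the overlap that comes from the shared controls was not measured by splitting them.

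The trace of donor cells was looked for through sex-linked genes, since the labels give the mice as male. Xist, the RNA that coats the inactive X chromosome of female cells (ENSMUSG00000086503), was present in every library, with 3779 to 9426 counts, and was not restricted to the patch with cells. Its CPM ranged from 259 to 469 in untreated skin, from 168 to 286 under the blank patch and from 197 to 220 under the patch with cells. The Y-linked genes Ddx3y, Eif2s3y and Uty had 0 to 3 counts per library and Kdm5d 6 to 12. These values go against the sex given in the labels for all 9 libraries, and no donor trace was read from them.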

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

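The tests of dilution and of deep tissue in this part were chosen only after the result was seen; the correlation with differences between mice of 1 group was chosen before. The genes below were taken because they were called against untreated skin in both treatments, in opposite directions. Their difference between the treatments was also called, and they stood in a fixed gene list. In all 41 genes moved this way, 31 of them higher with the blank patch and 10 higher with cells. A difference between the treatments follows from this choice, so the errors below describe its size and no p is given. Gfra3, a GDNF family receptor of nerve cells, was at a log2 fold change of 1.40 with the blank patch and -0.89 with cells, a difference of -2.29 ± 0.193 (SE). Postn, a matrix protein, was at 0.56 and -0.63, a difference of -1.20 ± 0.139. Cxcl10, the chemokine induced by interferon, was at 1.37 and -1.24, a difference of -2.61 ± 0.387. Ncam1, an adhesion molecule, was at 0.52 and -0.40, a difference of -0.92 ± 0.162. Ngfr, the low-affinity neurotrophin receptor, went the other way, at -0.44 and 0.52, a difference of 0.96 ± 0.128. Among the 41, Nlrp3, Nod2, Icam1, Nfkbia and Nfkb2 were chosen after their values were seen: all 5 were higher with the blank patch and lower with cells, with differences of -3.41, -2.05, -1.31, -1.14 and -0.53.

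Hair fibre and inner root sheath genes were higher, and sebaceous, muscle, matrix and immune genes lower, with cells than with the blank patch. A larger share of follicle RNA would lower all other tissue alike. The sebaceous list moved by -0.51 ± 0.127 (SE) more than the vessel list on the log2 scale, with no overlap of libraries. This argues against dilution as the whole cause, but rests on a single pair of lists. The vessel, mast cell, macrophage, adipocyte and smooth muscle lists lay close together, with mean log2 differences from -0.385 to -0.520. Matrix, dendritic cell and lymphocyte lists were at -0.731 to -0.783, skeletal muscle at -1.18 ± 0.423 and Schwann cells at -0.219 ± 0.0541 (SE). Dilution as a part of the cause stays open. Less of the deep muscle and fat in the skin pieces would leave the sebaceous glands in place, but their list had a median of -1.14. The list is not free of fat genes, since Pparg, Cidea and Elovl3 also stand in the adipocyte or brown adipocyte lists. Its mean log2 difference, -0.896 ± 0.0662, was larger in size than that of the adipocyte list, -0.459 ± 0.224 (SE). This argues against loss of deep tissue as the whole cause, within the limit of the shared genes. Differences between pairs of blank patch mice were set against the mean with cells minus the remaining blank patch library. Across genes they correlated at 0.286 or more in size. Pairs given cells, set against their remaining library minus the blank patch mean, gave 0.0683, 0.248 and 0.312. Untreated pairs, set against the contrast of both group means, gave at most 0.0388. Many hair genes were at 0 counts in untreated skin and could not part untreated mice, so these pairs are a weak benchmark. Some of the contrast may be position along an axis that also parts mice given the same patch, such as the stage of the hair cycle. An effect of the cells stays open, and was not separated from such a shift.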

How the results depend on the processing

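Directions of called results held under every alternative tried: of 1148 values of called lists, the estimated correlation aside, 1126 kept direction and call and 22 lost the call, and of 5620 values of called named genes 5445 kept both and 175 lost the call. A test against a 1.5-fold change, stricter by construction, left 3828, 700 and 7370 called genes for the blank patch against untreated skin, the patch with cells against the blank patch and the patch with cells against untreated skin, and 3616 genes shared in direction by both treatments; it ended 14 of 127, 59 of 117 and 5 of 131 named calls. With an estimated correlation 0, 0 and 0 lists were called, and with fry 32, 20 and 33. Leaving out 1 library gave 8221 to 9446, 2433 to 4319 and 11281 to 12116 called genes and 28 to 30, 23 to 25 and 28 to 29 called lists, and leaving out 1 untreated library 7567 to 8633 shared genes; for the patch with cells against the blank patch the count was 2438 without blank patch replicate 3, 2739 without replicate 1 of the patch with cells and 2433 without its replicate 2. DESeq2 called 9622, 5331 and 12093 genes, and edgeR with the replicate number as a block 9326, 4519 and 12041. Correlations of deviations from group means ran from -0.087 to 0.18 for libraries of the same number. For libraries of different numbers they ran from -0.232 to 0.091. Between the blank patch and the patch with cells the same-number pairs were at 0.18, 0.075 and 0.15. Whether the numbers pair the mice was not settled.

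The results that reversed were all lists and genes not called with all libraries, and the cause was not tested. For the blank patch against untreated skin, ribosomal protein genes turned with no count filter (camera adjusted p = 0.653) and on leaving out libraries (range 0.169 to 0.958). For the patch with cells against the blank patch, these lists turned when libraries were left out, with camera adjusted p ranging from 0.0344 to 0.871 for the cell cycle, 0.237 to 0.775 for Wnt, 0.228 to 0.838 for growth factors, 0.386 to 0.967 for Notch, 0.833 to 0.974 for basal keratinocytes (and 0.967 in fry), 0.0145 to 0.956 for wound keratinocytes and 0.051 to 0.838 for red blood cells. Mki67 ranged in log2 fold change from -0.303 to 0.011 and Bmp4 from -0.03 to 0.13, and Bmp4 was at -0.026 under upper-quartile factors. For the patch with cells against untreated skin, growth factors turned under the stricter count filter (camera adjusted p = 0.998), neutrophil genes on leaving out libraries (0.599 to 0.789), and red blood cell genes with no count filter (0.841) and on leaving out libraries (0.427 to 0.936). Depth leaves the folds of genes at 0 counts in a group as lower bounds. On simulated counts 17.9% of 1.5-fold changes were called with cells against the blank patch. Far fewer genes were changed there than were called in the data, so this share does not measure the sensitivity of that comparison.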

Other observations

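The tests of time of day, hair cycle stage and sex in this part were chosen only after the result was seen; the splits of the libraries were chosen before. Red blood cell genes did not move as 1 group. Slc4a1, the anion exchanger of red cells, had 2 counts in untreated skin, 703 with the blank patch and 2557 with cells, ratios of 342 (95% counting interval 94.33 to 2830) and 1297 (358.8 to 10720). Ahsp, a chaperone of alpha globin, was at 0 counts in untreated skin and at least 8.41-fold and at least 73.4-fold higher. The adult globin Hbb-bt was at 16.7 ± 4.80 CPM in untreated skin and 5.62 ± 2.74 CPM with cells (SD, n = 3; edgeR adjusted p = 0.00306). The list was not called in any comparison (camera adjusted p = 0.54, 0.628 and 0.996), and its medians of -0.32, -0.55 and -1.19 had the opposite sign to its means of 1.75, 0.06 and 1.81.

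Among the stress genes Hspa1a, an inducible heat shock protein, rose from 281 ± 75.9 CPM with the blank patch to 684 ± 98.5 CPM with cells, Dnajb1, a co-chaperone, from 138 ± 18.8 to 247 ± 14.5 CPM, and Hspb1, a small heat shock protein, from 310 ± 56.9 to 585 ± 107 CPM (SD, n = 3; edgeR adjusted p = 0.00228, 0.001 and 0.00431). Their technical list of heat shock and immediate early genes was not called (camera adjusted p = 0.141), with 6 of 23 members higher and 2 lower.

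Of 16 circadian clock genes 10 fell and 3 rose with the blank patch, and 13 fell and 3 rose with cells, against untreated skin, on either adjustment (adjusted p = 0.177 and 0.226 with an estimated correlation). With cells against the blank patch 9 were lower and 2 higher on either adjustment (adjusted p = 0.368 with an estimated correlation). Collection at another time of day could account for the blank patch, where 10 of 11 members driven by E-box and D-box elements were lower (median -1.19) and 3 of 5 driven by ROR elements were higher (median 0.81). With cells all 11 of the first kind were lower (median -1.64) and 3 of the 5 higher (median 1.09), which goes with it, whereas the other 2, Clock and Npas2, fell, which goes against it, so it stays open there too. An action of the hair cycle stage on the clock cannot be told apart from time of day, since each moves with the groups. The mean log2 CPM of Dbp, Nr1d1, Nr1d2, Tef and Hlf varied within groups by an SD of at most 0.143.

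Xist was high and Y-linked genes were near 0 in libraries labelled male. Counts of Ddx3y, Eif2s3y and Uty together were at most 0.0459% of those of their X-linked partners, which is what female mice, or a wrong sex label, would give. Kdm5d, with 6 to 12 counts per library, was not part of this share. Female donor cells as the whole source of Xist are argued against by untreated skin, where Xist was at 259.3 CPM or more. Loss of Y-linked reads in counting is argued against by the Xist counts of at least 3779, which male skin would not give. No other explanation was tested.

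The 6 libraries of each comparison can be divided into groups of 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many called genes: 9518 for the blank patch against untreated skin, with 0 as the highest other; 4650 for the patch with cells against the blank patch, with 1; and 12195 for the patch with cells against untreated skin, with 0.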
